A study of Caenorhabditis elegans with 3 samples.

How the data were processed

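Whole worms of 1 group, wild-type N2 at mid-L4, were measured in 3 libraries. Per the labels' protocols, RNA was extracted with Trizol and treated with DNase, ribosomal RNA was removed with Ribo-Zero Gold, and libraries were made with the TruSeq Stranded Total RNA kit. Per the submitters' processing notes, kallisto was used, which assigns reads to annotated transcripts without a genome alignment. Its version, the index, the genome build, the annotation release and how transcripts were summed to genes were not given in the sources used here. The deposited values were TPM per gene, which the authors computed for each library, and each column summed to 1000000. The authors also deposited a mean TPM per gene, which equalled the mean of the 3 columns with a largest difference of 6.67e-06. Because TPM divides by transcript length and by the library total, it holds no read count, so no count model or counting interval was used, and detection was a TPM limit that does not follow read depth.

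The 20392 sequence names were matched to Ensembl release 115 of the WBcel235 annotation. This matched 20133 names (98.7%), of which 19632 were protein-coding and 479 pseudogenes, and the 259 unmatched names held 0.204% of TPM. The authors may have used another annotation, so coordinates and transcript lengths describe WBcel235 and not necessarily the index behind the values. For 205 genes that shared a symbol, the RefSeq symbol was used. In 239 groups (513 genes) the values above 0 were identical in all libraries, and such copies cannot be told apart. Of 5 genes with such a copy under the rule for named genes, his-46, his-56, hsp-16.48 and hsp-16.49 moved by more than their SD when copies were summed to 1 value, and ehn-3 did not.

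Tests were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 on log2(TPM + 1), with a pseudocount of 1. Gene lists, the pairs of lists and the rule for named genes were fixed before the data were examined. The rule named the 15 genes with the highest mean TPM, the 10 with the largest coefficient of variation at a mean of at least 10 TPM, the 5 with the smallest at a mean of at least 100 TPM, the 3 highest and the lowest of each list (6 highest for the sperm and oocyte lists, every member of lists of up to 6), and every dot-1 and zfp-1 gene. The text names a selection of these. List levels were set against 10000 random lists, list pairs and chromosomes were tested with 100000 resamples, or with every split where a list had fewer than 10 genes, and variation was set against 10000 lists matched on 10 bins of mean expression among genes with a mean of at least 1 TPM. All tests were two-sided with a threshold of 0.05 after Benjamini-Hochberg adjustment. They ran across genes, which are not independent replicates, so the p-values describe these libraries. The exception was Fisher's exact test of list genes on X, which used annotated positions and no TPM value.

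Some matching choices were made after the values had been seen. The mitochondrial list was taken as the 12 protein-coding genes of the mitochondrial genome, because the symbols fixed for it were not used in the naming tables. Lists defined by a pattern accepted a symbol from either naming table, his-24 was kept in the variant and linker list alone, and rpl-36.A and Y37E3.8, which RefSeq names as ribosomal protein genes, stayed outside the ribosomal list because the pattern did not match them. The names trp-3, daf-21, rde-3, elt-5, opt-2, unc-17, prg-2 and wago-11 matched no gene under that symbol. Several lists overlap, such as the bli genes in the adult cuticle and collagen lists. Excluding genes with a transcript under 300 nt, leaving the 4 germ line lists out of the X comparison, filtering list genes and random lists alike and testing families by symbol prefix were also chosen after the values had been seen.

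The tests were tested on simulated data. For replicate variation, all 11 lists given a library shift of 1 log2 unit were found among 13530 genes, and 0 of 22 unshifted lists were called. The noise of the simulated genes was independent. The 0 of 22 therefore does not show how often lists of genes that move together would be called. For list levels across 20392 genes, 5 of 11 lists drawn from the more abundant genes were found and 0 of 22 others were called. For pairs of lists of 45 genes in all, a difference of 3 log2 units was found in 96 of 100 simulations, and 6 of 100 pairs without a difference passed an unadjusted threshold of 0.05. The alternatives were other pseudocounts (0.1 and 5), other detection limits (0.5 and 5 TPM), other gene filters, median-of-ratios rescaling, totals without the most abundant genes, the list mean, another measure of spread, and leaving out each replicate. The planned share of the dominant transcript was not computed, because the values are per gene.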

Results

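RNA abundance was measured by sequencing ribosomal-RNA-depleted total RNA of whole Caenorhabditis elegans of the wild-type strain N2 at the middle of the fourth larval stage (L4). The worms had grown for 29 h after synchronization at 25 °C on the bacterial food strain OP50. Cultures of N2 consist mostly of self-fertile hermaphrodites, which make sperm during L4 before they switch to oocytes. The series held 1 group of 3 libraries, described by the submitters as independent, so no treatment or genotype was compared. The values were TPM, a transcript abundance normalised to transcript length and library total, for 20392 genes, and each library summed to 1000000 TPM. TPM keeps no read depth, so the depth behind each value is unknown, and errors are given as the SD over the 3 libraries. Gene positions are from a match of sequence names to the WBcel235 annotation, since the build used by the authors was not given in the sources used here.

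Among the gene lists, ribosomal proteins held the largest share of TPM, which is divided by transcript length and is not a share of RNA mass. The 78 genes of the cytosolic ribosomal protein list held 42.9% ± 0.707 (SD, n = 3) of all TPM. The most abundant was rpl-29 (chromosome IV, 13882225 to 13882618), a gene of the large ribosomal subunit, at 55327 ± 2745 TPM (SD, n = 3). It was followed by rpl-39 (chromosome V, 7775742 to 7776079) at 47320 ± 2613 TPM, rps-28 (chromosome IV, 1659691 to 1659997) at 35855 ± 969 TPM, rpl-38 (chromosome V, 15512166 to 15512737) at 33106 ± 1837 TPM and rpl-13 (chromosome I, 3788036 to 3788896) at 22580 ± 1020 TPM. These 5 genes have an annotated transcript under 300 nt, which for rpl-29 is 96 nt. Of the 15 most abundant genes, all but F23A7.4 and F23A7.8 carry a ribosomal protein symbol in at least 1 of the naming tables used. F23A7.4 (X, 16212606 to 16212812) stood at 18994 ± 1546 TPM and F23A7.8 (X, 16213373 to 16213576) at 5782 ± 1103 TPM, and their shortest annotated transcripts measure 207 and 204 nt. The remaining ribosomal genes among the 15 were Y37E3.8, W01D2.1, rps-29, rpl-12, rpl-43, rpl-36.A, rps-21 and rpl-32, with means between 6063 and 17813 TPM. The lowest member of the list, rpl-42, had 1.47 ± 0.807 TPM. Core histone genes held 4.84% ± 0.386 of all TPM, led by his-46 and his-56, which had identical values of 5732 ± 581 TPM (11465 TPM summed) and cannot be separated, and by his-66 at 3151 ± 296 TPM. Cuticle collagens held 1.51% ± 0.553, the 12 protein-coding mitochondrial genes 0.623% ± 0.0113 and the major sperm proteins 0.119% ± 0.0900. The share of the major sperm proteins was 0.221%, 0.0864% and 0.05002% in replicates 1, 2 and 3, and 0.0682% without replicate 1. Shares depend on the total. Without the 100 most abundant genes they were 5.12% for core histones, 2.84% for cytosolic ribosomal proteins, 3.42% for collagens, 1.41% for mitochondrial genes and 0.268% for major sperm proteins. Without genes with a transcript under 300 nt, cytosolic ribosomal proteins held 29.6%, core histones 7.35%, collagens 2.31%, mitochondrial genes 0.943% and major sperm proteins 0.137%.

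A gene counted as detected at 1 TPM or more in all 3 libraries, which 12454 genes (61.1%) reached. The libraries held 13444, 13322 and 13172 genes at that level, and 1262 genes were listed at 0 in all of them. The 10 most abundant genes of each library held 25.0%, 26.5% and 26.2% of its TPM. Across genes, log2(TPM + 1) correlated with Pearson's r = 0.980 between replicates 1 and 2, 0.981 between replicates 2 and 3, and 0.956 between replicates 1 and 3. Genes are not independent replicates, so these values carry no p-value. The SD of the log2 difference was 0.44, 0.43 and 0.65 for the same pairs. The median coefficient of variation of a detected gene was 12.1%, and 1921 detected genes differed at least 2-fold between their highest and lowest library. The genes that varied least among those at 100 TPM or more were the small ribosomal subunit gene rps-2 (1131 ± 3.01 TPM), the cytochrome c oxidase gene cox-5B (538 ± 2.65), ahsa-1 (114 ± 0.778), the 14-3-3 gene par-5 (413 ± 2.88) and the aspartyl protease gene asp-3 (723 ± 5.38).

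Gene lists fixed in advance were compared with 10000 random lists of the same size drawn from all measured genes. Of 36 lists, 16 lay above the random lists and 4 below (permutation test across genes, two-sided, Benjamini-Hochberg adjusted over the 36 lists). Against random lists of genes with a mean of at least 1 TPM, 12 lay above and 8 below, but the members of the tested lists were not filtered there, which moves lists with weak members down by construction. With the filter applied to both, an alternative chosen after the data had been seen, 13 of 33 lists lay above and 0 below. Cytosolic ribosomal proteins, mitochondrially encoded subunits and core histones stood highest. The median log2(TPM + 1) was 11.52 ± 0.05 (SD, n = 3) for cytosolic ribosomal proteins, 8.21 ± 0.19 for mitochondrially encoded subunits, 7.58 ± 0.23 for core histones, 6.88 ± 0.05 for constitutive chaperones, 6.38 ± 0.08 for reference genes of quantitative PCR, 6.27 ± 0.19 for proteasome subunits and 5.27 ± 0.09 for mitochondrial ribosomal proteins. Each of these 7 lists had adjusted p = 0.000654 in the permutation test, the lowest value any list reached. It rests on an unadjusted permutation p of 0.0002, the smallest that 10000 random lists give, and so does not rank the lists. Muscle and intestine markers had the same adjusted p, at 7.03 ± 0.10 and 6.60 ± 0.06. The muscle list was led by the troponin C gene pat-10 (1498 ± 54.4 TPM), the myosin heavy chain gene unc-54 (678 ± 7.27) and the myosin light chain gene mlc-3 (578 ± 12.1), while the transcription factor gene hlh-1 had 2.74 ± 0.0425 TPM. The intestinal list was led by the metallothionein gene mtl-2 (2117 ± 370 TPM), the protease gene asp-1 (1849 ± 189) and the actin gene act-5 (673 ± 10.04), and its lowest member was the GATA factor gene elt-7 (5.08 ± 0.353).

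Of the 4 lists below the random lists, 3 were lists of genes known from other stages or from males, and the remaining list was that of the cuticle collagens. The 9 embryonic zygotic genes had a median of 0.03 ± 0.03 and none was detected, with the endoderm gene end-3 highest at 0.110 ± 0.0676 TPM (permutation adjusted p = 0.00332). The dauer and first larval cuticle genes stood at 0.03 ± 0.03, again with 0 of 4 detected (permutation adjusted p = 0.0304). Of these, cut-3 averaged 0.102 ± 0.0201 TPM, col-2 and col-40 were above 0 in 1 library each, and cut-1 was listed at 0 in all libraries. The 7 genes of male-specific neurons stood at 0.07 ± 0.06, none was detected, and the polycystin genes pkd-2 and lov-1 had 0.0716 ± 0.0331 and 0.00535 ± 0.000881 TPM (permutation adjusted p = 0.0472). Cuticle collagens, at 1.47 ± 0.13, were also below (permutation adjusted p = 0.0301), although 89 of 177 were detected and col-117, col-3 and col-167 reached 1654 ± 824, 1396 ± 744 and 902 ± 480 TPM. With the filter of 1 TPM applied to both, the 101 collagens left lay above the random lists instead (permutation adjusted p = 0.000733), and the other 3 lists had fewer than 2 genes left and were not tested. The number of lists below fell to 2 without replicate 1, where collagens (permutation adjusted p = 0.0727) and male-specific neurons (p = 0.0633) did not pass, and to 1 without replicate 3, where these (p = 0.0747 each) and the dauer and first larval cuticle genes (p = 0.052) did not.

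**Figure D1:**
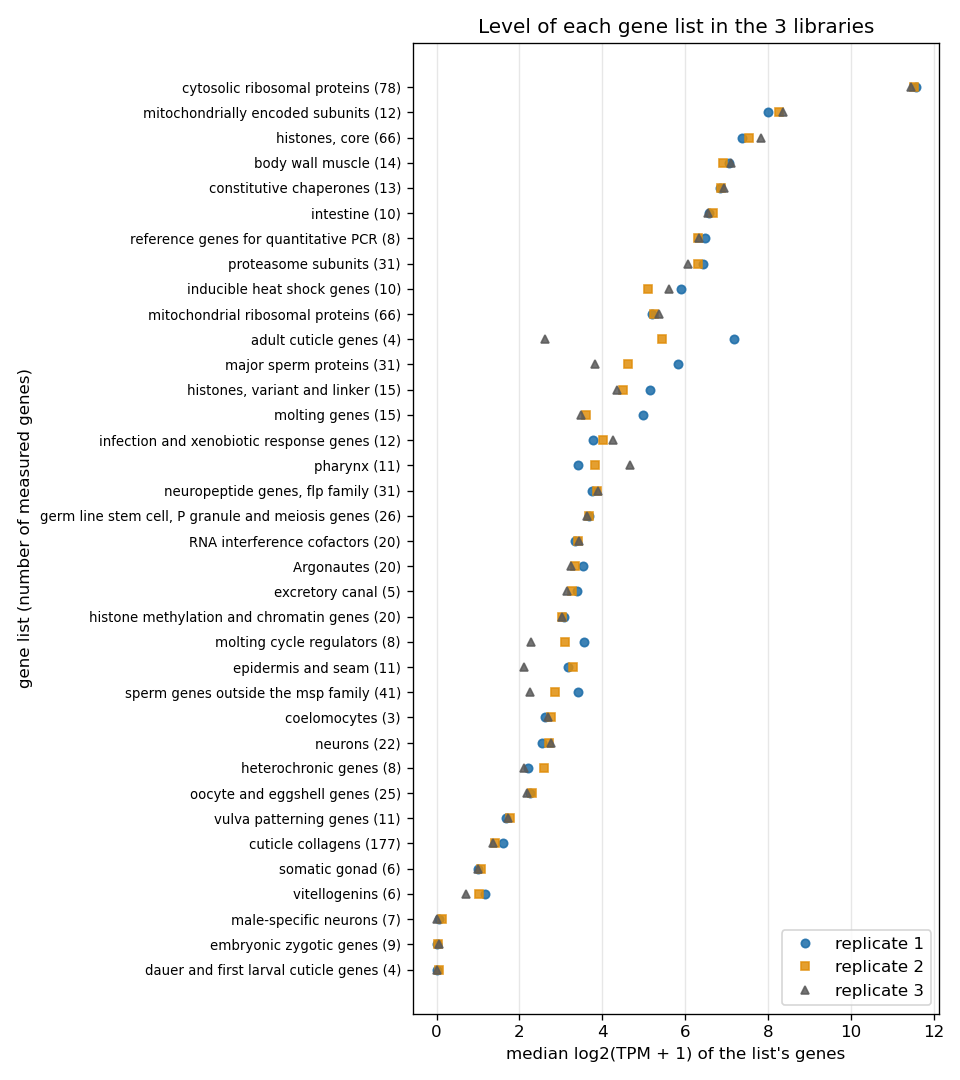
Median log2(TPM + 1) of each gene list (horizontal axis) in each of the 3 libraries (1 point per library), with the number of measured genes in brackets. Ribosomal proteins lie highest at 11.52, and the points spread most for the adult cuticle genes, whose SD was 2.30.

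Germ line genes were present at moderate levels, with sperm genes more abundant in some libraries than in others. The major sperm proteins, the cytoskeletal proteins of nematode sperm, had a median of 4.76 ± 1.02, with 29 of 31 detected and a permutation adjusted p of 0.000654. The highest were msp-58 (245 ± 168 TPM), msp-31 (95.5 ± 76.1) and msp-40 (64.5 ± 45.9), and members with near-identical sequences are uncertain. Replicate 1 carried these means, with 437, 180 and 120 TPM for msp-58, 182, 65.8 and 38.8 for msp-31, and 115, 54.4 and 24.5 for msp-40 in replicates 1, 2 and 3. The annotated transcript of msp-58 measures 234 nt, and those of msp-31 and msp-40 measure 384 nt. Sperm genes outside this family were set apart by symbol alone, as listed sperm genes without an msp symbol. They stood at 2.84 ± 0.58 with 32 of 41 detected, which did not pass (permutation adjusted p = 0.231). They were led by msd-3 (50.2 ± 43.3 TPM), msd-4 (38.2 ± 26.98), ssp-9 (37.8 ± 28.4), ssp-16 (36.4 ± 18.1), spch-3 (30.3 ± 18.5) and msd-2 (29.6 ± 22.7), and spe-12 was lowest at 0.739 ± 0.358. Replicate 1 was highest here as well, with 99.6, 31.8 and 19.2 TPM for msd-3. Oocyte and eggshell genes stood at 2.24 ± 0.07 with 22 of 25 detected, and did not pass either (permutation adjusted p = 0.841). Their highest members were the eggshell gene cbd-1 (19.2 ± 1.59 TPM), spn-4 (9.74 ± 0.285), the chondroitin proteoglycan genes cpg-1 (9.41 ± 0.224) and cpg-2 (8.35 ± 0.800), and the katanin genes mei-1 (8.24 ± 0.270) and mei-2 (7.95 ± 0.376), while perm-4 had 0.257 ± 0.189. Germ line stem cell, P granule and meiosis genes, all 26 detected, had a median of 3.67 ± 0.03 (permutation adjusted p = 0.0168, lost at p = 0.354 with the filter of 1 TPM applied to both), led by him-8 (128 ± 8.43 TPM), rec-8 (62.1 ± 4.22) and glh-1 (41.2 ± 4.52). The shortest annotated transcripts of him-8 and rec-8 measure 120 and 75 nt. Vitellogenins, the yolk proteins of adults, stood at 0.97 ± 0.24 with 3 of 6 detected, from vit-1 at 6.76 ± 3.84, vit-6 at 5.86 ± 3.21 and vit-2 at 2.74 ± 1.14 down to vit-4, vit-3 and vit-5, which averaged 0.0532, 0.0423 and 0.00854 TPM (permutation adjusted p = 0.416).

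The sperm list outside the major sperm protein family exceeded the oocyte list by 0.60 in median log2(TPM + 1), a difference that did not pass the test (permutation test across 41 and 25 genes, two-sided, p = 0.220, adjusted p = 0.242 over 11 list pairs). It was above 0 in 3 of 3 libraries, at 1.16, 0.55 and 0.09. The difference was 0.36 without replicate 1. The sperm list lay 0.86 below the germ line stem cell, P granule and meiosis genes (permutation adjusted p = 0.0451), in 3 of 3 libraries, but this did not pass without replicate 2 (p = 0.0555) or without replicate 3 (p = 0.181), nor with a pseudocount of 5 (p = 0.0648) or with only list genes of at least 1 TPM (p = 0.059).

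Other pairs of lists, except Argonautes and RNA interference cofactors, differed by more. Cytosolic ribosomal proteins exceeded mitochondrial ones by 6.23 (per library mean 6.25 ± 0.14, SD, n = 3, permutation adjusted p = 0.00011). Body wall muscle markers exceeded neuronal markers by 4.33 (4.35 ± 0.16, permutation adjusted p = 0.000275), intestine markers exceeded vitellogenins by 5.61 (5.63 ± 0.23, exact permutation adjusted p = 0.0326) and core histones exceeded variant and linker histones by 2.80 (2.91 ± 0.63, permutation adjusted p = 0.00986). Molting genes exceeded embryonic zygotic genes by 3.51 (4.003 ± 0.86, exact permutation adjusted p = 0.0383). Neuronal markers exceeded those of male-specific neurons by 2.58 (2.61 ± 0.14, exact permutation adjusted p = 0.0383), a call lost without replicate 3 (p = 0.0547). Constitutive chaperones exceeded inducible heat shock genes by 1.32 (1.34 ± 0.42, permutation adjusted p = 0.0428), a call lost without replicate 2 (p = 0.0666). With a pseudocount of 5, the calls for chaperones, molting against embryonic genes and intestine against vitellogenins (permutation adjusted p = 0.0648 each) and for neurons against male-specific neurons (p = 0.133) were lost. With only list genes of at least 1 TPM, those for chaperones and for core against variant histones (permutation adjusted p = 0.059 each) and intestine against vitellogenins (p = 0.247) were lost, and with list means that for chaperones was (p = 0.0601). These differences had the same sign in 3 of 3 libraries. Adult cuticle genes exceeded dauer and first larval cuticle genes by 5.13 (5.05 ± 2.28), which did not pass in the exact permutation test of 4 against 4 genes (adjusted p = 0.105). With medians of 4 against 4 genes, not even complete separation gives p under 0.05 in that test. It therefore cannot decide whether these 2 lists differ. Argonautes and RNA interference cofactors differed by -0.09 (-0.03 ± 0.20, permutation adjusted p = 0.818). The Argonaute list, at 3.38 ± 0.15, was led by prg-1 (59.6 ± 2.95 TPM), wago-1 (47.3 ± 4.57) and ppw-1 (46.3 ± 5.14), and the cofactors, at 3.41 ± 0.05, by rde-4 (24.1 ± 1.78), ekl-1 (18.1 ± 0.497) and drh-1 (14.5 ± 0.437). Neither list passed the level test (permutation adjusted p = 0.110 and 0.0887).

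Heat shock genes were abundant in all libraries. The inducible heat shock genes had a median of 5.53 ± 0.41 with 9 of 10 detected (permutation adjusted p = 0.000654). The small heat shock gene hsp-16.1 (chromosome V, 9087293 to 9087782) had 531, 357 and 584 TPM in replicates 1, 2 and 3, and hsp-16.48 and hsp-16.49, which had identical values, averaged 298 ± 60.7 TPM (596 TPM summed). All 9 detected genes were lowest in replicate 2, as were 4 of the 13 constitutive chaperones, of which hsp-90 (749 ± 24.4 TPM), hsp-1 (691 ± 35.3) and hsp-3 (662 ± 93.4) were the most abundant. Infection and xenobiotic response genes stood at 4.02 ± 0.24 (permutation adjusted p = 0.0304, lost without replicate 3 at p = 0.0599 and with the filter of 1 TPM applied to both at p = 0.0572), with the highest means in sysm-1 (71.4 ± 66.4 TPM), irg-5 (66.0 ± 32.4) and irg-4 (41.1 ± 9.55). Of these sysm-1 had 148, 39.1 and 27.3 TPM in replicates 1, 2 and 3, and was the lowest of the 3 in replicates 2 and 3.

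X-linked genes were less abundant than autosomal genes. Among detected protein-coding genes, 1592 X-linked genes had a median log2(TPM + 1) of 2.97 and 10626 autosomal genes 3.46, a difference of -0.48 that was -0.52, -0.43 and -0.47 in the 3 libraries (permutation test across genes, two-sided, p = 1e-05, the smallest that 100000 resamples give). The share of measured genes detected was 59.7% on X and 62.7% on autosomes. Single autosomes ranged from 47.6% (V) to 79.3% (III), so the detected share of X lay within their range. Among genes with a mean of at least 5 TPM the difference was -0.14. No gene of the 4 germ line lists was X-linked: 0 of 31 major sperm protein genes, 0 of 41 other sperm genes, 0 of 25 oocyte and eggshell genes and 0 of 26 germ line stem cell, P granule and meiosis genes. Of the genes outside each list 13.6% were on X (Fisher's exact test, two-sided, adjusted p = 0.0339, 0.019, 0.0409 and 0.0409 over the 4 lists). This test used list membership and annotated position and no TPM value. It therefore describes the genes chosen for the lists and not their RNA abundance.

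Cuticle, molting and sperm genes varied more between the 3 libraries than genes of similar abundance. Against random lists matched on mean expression, 5 of 33 lists had a higher median SD of log2(TPM + 1) and 5 a lower one (permutation test, two-sided, adjusted over the 33 lists). Adult cuticle genes had a median SD of 2.18 against 0.14 in matched lists, cuticle collagens 1.07 against 0.15, major sperm proteins 1.06 against 0.15, molting genes 0.96 against 0.15 and other sperm genes 0.62 against 0.17, each with permutation adjusted p = 0.0011. The unadjusted permutation p of each was 0.0002, the smallest that the random lists give. Vitellogenins had a median SD of 0.73 and did not pass (permutation adjusted p = 0.087). The cuticle collagens bli-6, bli-2 and bli-1, named for the blistered cuticle of their mutants, had 265, 66.5 and 6.03 TPM, 189, 62.2 and 10.1 TPM, and 109, 28.6 and 4.40 TPM in replicates 1, 2 and 3, while col-19, the remaining gene of the adult cuticle list, was below 0.05 TPM. The molting genes noah-1, noah-2 and lpr-3 averaged 229 ± 134, 195 ± 110 and 118 ± 67.4 TPM, and nas-36 2.64 ± 1.63. All 29 detected major sperm protein genes and all 32 other detected sperm genes were highest in replicate 1, as were 12 of 15 molting genes. Markers of the epidermis and seam deviated by 0.31, 0.04 and -0.36 in replicates 1, 2 and 3, and those of the pharynx by -0.21, 0.02 and 0.19, with 8 of 9 detected members highest in replicate 3, and neither list passed the variation test (permutation adjusted p = 0.229 and 0.404). Cuticle collagens went both ways, with 40 detected members highest in replicate 1 and 46 in replicate 3. Among genes with a mean of at least 10 TPM, the 10 with the largest coefficient of variation were all highest in replicate 3, and were nspb-2, nspb-6, nspb-8, nspb-10, nspb-11, nspb-12, F09B12.7, grl-21, col-130 and col-162. Of these nspb-2 had 8.67, 12.8 and 191 TPM in replicates 1, 2 and 3.

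**Figure D2:**
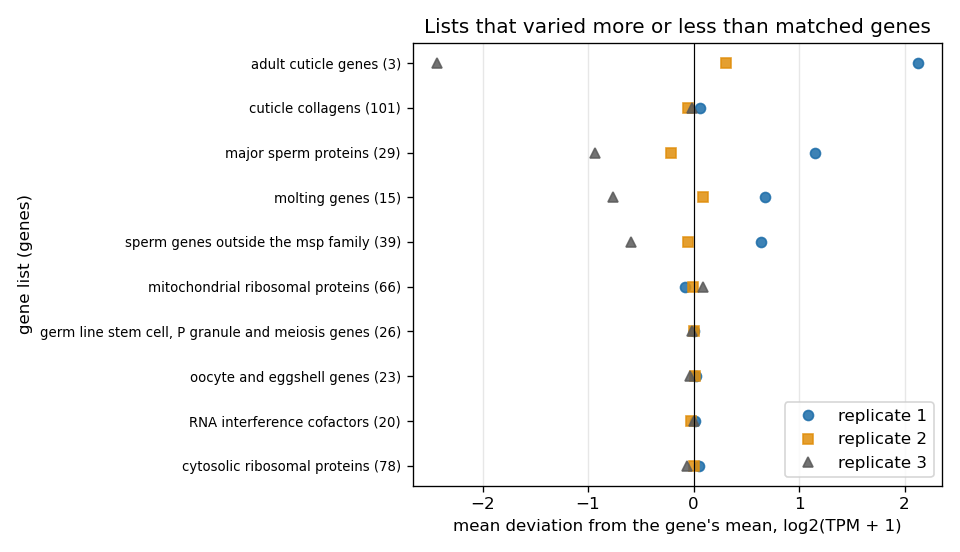
Mean deviation of each list's genes from their own mean over the 3 libraries, in log2(TPM + 1) (horizontal axis), for the 10 lists that varied more or less than matched genes; each point is 1 library and brackets give the number of genes. Adult cuticle genes lay at 2.13, 0.31 and -2.44, while cuticle collagens lay near 0 because their members went both ways.

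The lists that varied less than matched genes were cytosolic ribosomal proteins (median SD 0.07, permutation adjusted p = 0.0011), oocyte and eggshell genes (0.08, p = 0.00566), RNA interference cofactors (0.07, p = 0.0124), mitochondrial ribosomal proteins (0.10, p = 0.0383) and germ line stem cell, P granule and meiosis genes (0.09, p = 0.0383). The number of less variable lists fell to 2 without replicate 1, 3 without replicate 2 and 2 without replicate 3, and of these 5 lists cytosolic ribosomal proteins passed each time. Germ line stem cell, P granule and meiosis genes also did not pass after median-of-ratios rescaling (permutation adjusted p = 0.0534), and neither they (p = 0.0749) nor the oocyte list (p = 0.094) passed among genes with a mean of at least 5 TPM. Molting cycle regulators, at a median level of 2.97 ± 0.65, and inducible heat shock genes did not pass, with median SDs of 0.45 and 0.42 and a permutation adjusted p of 0.0519 each. Among the regulators, myrf-1 (15.1 ± 2.33 TPM), blmp-1 (9.60 ± 1.51) and nhr-23 (9.10 ± 1.81) were highest and nhr-25 lowest (0.403 ± 0.261).

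Chromatin and developmental regulators were expressed at low to moderate levels. Histone methylation and chromatin genes stood at 3.04 ± 0.03 (permutation adjusted p = 0.231 for their level), with hpl-2 (27.7 ± 0.686 TPM), mes-3 (14.6 ± 0.672) and hda-1 (13.01 ± 0.609) highest. The gene zfp-1 (chromosome III, 8791535 to 8806305) had 11.7 ± 1.64 TPM. Of the dot-1 genes, dot-1.1 (chromosome I, 2382953 to 2401492) had 7.44 ± 0.403 TPM and dot-1.3 2.50 ± 0.846, dot-1.2 and dot-1.4 averaged 0.121 ± 0.0878 and 0.0916 ± 0.0521, and dot-1.5 was listed at 0 in all libraries. Heterochronic genes stood at 2.31 ± 0.25 (permutation adjusted p = 0.736), with lin-28 at 9.64 ± 0.401, lin-42 at 9.004 ± 6.61 (15.9, 8.47 and 2.67 TPM in replicates 1, 2 and 3) and lin-14 at 7.26 ± 1.88 TPM. Vulva patterning genes stood at 1.72 ± 0.05 (permutation adjusted p = 0.771), led by let-23 (6.63 ± 0.543 TPM) and cdh-3 (6.10 ± 0.867). Variant and linker histones stood at 4.67 ± 0.42 (permutation adjusted p = 0.0024), with his-72 at 169 ± 5.70 and htz-1 at 99.8 ± 11.6 TPM.

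Among the remaining tissue markers, the flp neuropeptide genes lay above random lists at 3.84 ± 0.07 (permutation adjusted p = 0.00514, lost at p = 0.163 with the filter of 1 TPM applied to both), with flp-1 at 40.8 ± 7.64 TPM. Neuronal markers stood at 2.68 ± 0.12 (p = 0.470 in the permutation test, adjusted), led by snb-1 (48.9 ± 3.54 TPM), unc-64 (33.2 ± 1.06) and egl-21 (33.0 ± 1.70). Adult cuticle genes stood at 5.08 ± 2.30 (permutation adjusted p = 0.0466, lost without replicate 1 at p = 0.210, without replicate 2 at p = 0.0583 and with the filter of 1 TPM applied to both at p = 0.141). Pharynx markers at 3.97 ± 0.64 (permutation adjusted p = 0.0706), led by myo-1 (89.7 ± 8.90 TPM), did not pass, nor did molting genes at 4.03 ± 0.83 (p = 0.110) and epidermis and seam markers at 2.86 ± 0.65 (p = 0.265), led by wrt-10 (183 ± 89.8 TPM). Without replicate 1 the pharynx list passed (permutation adjusted p = 0.033), and without replicate 3 the molting list passed (p = 0.0126). Excretory canal markers at 3.27 ± 0.13, led by aqp-8 (81.6 ± 15.7 TPM), coelomocyte markers at 2.70 ± 0.08, led by cup-4 (9.48 ± 0.934), and somatic gonad markers at 1.03 ± 0.04, led by lim-7 (2.91 ± 0.254), did not pass either (permutation adjusted p = 0.470, 0.771 and 0.444). The annotated transcripts of aqp-8 range from 156 to 1714 nt.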

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

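The alternatives without short transcripts, for shares and for X, the X difference without the germ line lists and the filter of 1 TPM on both random lists and list genes were chosen after the data had been seen. TPM hides depth, so no result could be weighted by it. The X difference kept its sign and passed under 10 of 10 alternatives, from -0.53 to -0.14, and the sperm and oocyte difference did not pass under any of 7 (0.36 to 0.83). The cause of the changes below was not tested unless stated.

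Detected genes numbered 8037 at 5 TPM. Mean r was 0.950 for genes with a mean of at least 1 TPM, and 0.956 to 0.981 when 1 replicate was left out. Without the 100 most abundant genes in the total, shares were 0.268% for major sperm proteins, 3.42% for collagens, 2.84% for cytosolic ribosomal proteins and 1.41% for mitochondrial genes, by construction. Without genes with a transcript under 300 nt they were 2.31% for collagens, 7.35% for core histones, 29.6% for cytosolic ribosomal proteins and 0.943% for mitochondrial genes. With random lists alone from genes of at least 1 TPM, 12 lists lay above and 8 below, and the oocyte list turned from the 58.0th to the 0.81 percentile, which the unlike filter favours. With the filter on both, 13 lists lay above and 0 below, the collagens turned from the 0.66 to the 100th percentile, and 3 lists had too few genes. When 1 replicate was left out, lists below numbered 1 to 4.

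With a pseudocount of 5, the pairs that no longer passed were chaperones (1.25), molting and embryonic genes (1.67), neurons and male neurons (1.04), intestine and vitellogenins (4.002), and sperm and germ line genes (-0.58). With list genes of at least 1 TPM they were chaperones (1.26), histones (2.19), intestine and vitellogenins (3.91), and sperm and germ line genes (-0.83). With list means it was chaperones (1.65). When 1 replicate was left out, chaperones ranged from 1.09 to 1.51, sperm and germ line genes from -1.13 to -0.56, and neurons and male neurons from 2.50 to 2.63.

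Lists less variable numbered 3 at 5 TPM or more and 2 to 3 when 1 replicate was left out, and lists more variable numbered 8 with the median absolute difference. Of single lists, 226 level results stayed on their side of the threshold, passing or not, 16 no longer passed and 5 newly passed. A further 2 were counted as reversed, of which the oocyte list had not passed as reported. Lists that passed in neither setting may have changed direction among the 226. For variation, 230 results stayed on their side of the threshold, 13 no longer passed and 17 newly passed.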

Other observations

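Families named by a shared symbol prefix, tested after the values had been seen, added groups to those that varied between libraries. Of 160 families with at least 8 members at a mean of 1 TPM or more, 18 varied more and 13 less than genes matched on expression (permutation test, two-sided, adjusted over the families). Not all of these are additions. The 18 include the msp, col, mlt, spe and ssp families and the 13 include rpl and rps, which share members with the lists fixed in advance. The nspb genes summed to 61.8, 156 and 1235 TPM in replicates 1, 2 and 3, and 11 of 11 were highest in replicate 3. The fipr genes summed to 2233, 4226 and 9936 TPM, with 20 of 24 highest in replicate 3. The nspd genes went the other way, at 896, 357 and 207 TPM with 9 of 9 highest in replicate 1. So did the hedgehog-related wrt genes, at 482, 296 and 133 TPM with 6 of 8 highest in replicate 1. The nspb, fipr, nspd and wrt families each had permutation adjusted p = 0.0032, the lowest value any family reached. That test compared the SD of a family with matched genes, and neither the direction nor the sums were tested.

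All tests in the following paragraphs were chosen after the results they bear on had been seen, and with 1 group no biological explanation was tested.

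Sperm, adult cuticle and molting genes were higher in replicate 1 than in replicate 3 in 77 of 79 detected members, with a median log2 difference of 1.87. These lists were picked for that direction, so the count partly restates the choice. The list of cuticle collagens, which also varied more than matched genes, was not pooled with them. Of its detected members, 40 were highest in replicate 1 and 46 in replicate 3. Each library was scaled to the same TPM total, which removes a common factor, so a test of scaling could hardly have found one. The median log2 difference of all 12454 detected genes was -0.0114, so genes in general did not shift with these lists. A bias by transcript length is argued against, since in the bin of detected genes farthest from 0, of 20 length bins, the median was -0.0707. A difference in developmental age between the collections may lie behind the pattern, but no value here separates it from other graded differences between cultures.

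The 5 most abundant ribosomal protein genes held 45.3% of the list's TPM and 19.4% of all TPM. Reads from structural RNAs inside these genes are argued against, since 0 of the 5 overlap an annotated structural RNA on the same strand. Short transcripts may explain part of the pattern, because TPM divides by a length that is uncertain for them. The 13 ribosomal protein genes with a transcript under 300 nt had a median TPM 2.75 times that of the 65 others (permutation p = 1e-05, the smallest possible), and the 8 left without the 5 genes 1.98 times. The 13 include the 5 genes whose height prompted the test, so the p-value partly restates that height. The 8 were not tested on their own. Genes were grouped by their shortest annotated transcript, and rpl-13, grouped by 267 nt, also has a transcript of 664 nt. A true excess of the RNAs of the short genes would give the same ratio, so it stays open as well.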
